A study of Mus musculus with 36 samples.

How the data were processed

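Total RNA of 36 mouse samples was measured on Affymetrix expression arrays of 22690 probe sets, 24 arrays of primary microglia and 12 of BV-2 cells. Per the labels, RNA was isolated with a column kit, labelled with biotin by a 3' one-cycle amplification, and taken from cells left untreated or incubated with 500 U/ml IFN-b for 6 h or 24 h. The authors' processing notes name affy; its version, the summary method and the normalization are not given in the sources used here. The deposited values are log2 intensities by their range (1.664 to 14.031), an inference, since the log base is not stated. Array medians ran from 5.594 to 5.827, and the mean array medians of any 2 compared groups differed by at most 0.086 in size. Values were used as deposited. The number of arrays, 2 in each of 18 groups, limits the precision of the comparisons.

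Groups were taken from the sample labels. The 6 WT titles occur in 2 runs of the deposition order, which falls into 3 runs of 12 arrays: KO with WT (set 1), BV-2, and C61A with WT (set 2). The labels do not say what the runs are, and they were used as a candidate technical batch only. No 2 arrays held identical values (highest correlation 0.995). Correlations of WT arrays within and between sets were computed over 14222 probe sets.

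Of the probe sets 21084 were listed in the probe table, 20393 of them with 1 gene and 691 with several, and 1606 were not listed. Probe sets with several genes or none were left out, which left 12394 genes, and no symbol changed when checked against the RefSeq gene names. A probe set was kept when its value lay above its array's median on at least 2 arrays of the fit, and a gene was read by its kept probe set with the highest mean, leaving 7960 genes in microglia and 7163 in BV-2 cells. Other probe sets of a named gene were checked for direction.

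Comparisons were made with limma 3.58.1 in R 4.3.3, by a linear model of group means with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p under 0.05 as the threshold. The microglia fit held 24 arrays in 12 cells of genotype, time and set, the BV-2 fit 12 in 6 groups. Residual degrees of freedom (12 and 6) ignore cultures sampled repeatedly. WT responses were the mean over the 2 sets. The KO and C61A arrays were compared with WT of their own set, responses to IFN-b were compared between genotypes and between siRNAs by interaction terms, and the KO effect was compared with the C61A effect by the difference of the 2 contrasts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

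The 23 gene lists held 357 genes, 306 of them on the array: antiviral effectors, ISG15 conjugation, interferon receptor and JAK-STAT signalling, nucleic acid sensing, GTPases, chemokines, class I and class II antigen presentation, inflammatory cytokines and co-stimulators, markers of resting microglia, phagocytic and lysosomal genes, complement, cell cycle, cell death, cholesterol synthesis, endoplasmic reticulum stress, and markers of astrocytes, oligodendrocytes, neurons, fibroblasts and endothelium, border macrophages, monocytes and granulocytes, and lymphocytes. Members past the threshold were counted over all genes and with adjustment over the list alone, and lists were tested by camera with a preset correlation of 0.01 and with an estimated correlation. Genes that responded to IFN-b in WT arrays of the other set or cell system (adjusted p under 0.05, log2 change of at least 1) were followed as independent lists. The groups, comparisons, lists and the rule for naming genes were fixed before the data were examined. For each comparison the rule admits up to 10 genes with the largest change in each direction whose arrays do not overlap between groups, up to 4 called members of each list, and Usp18. The text names those of them whose calls held best when single arrays were left out, together with the leading genes of each paragraph's biology. This last choice among the admitted genes was made after the results and the leave-one-out fits had been seen, and the list of named genes was shortened in that step, so the numbers of named genes that kept or lost their calls describe the named genes only and can overstate the stability of the called genes as a whole.

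Deviations of replicates from group means were correlated between groups to check whether numbers pair arrays. In WT these correlated at 0.434 to 0.672 across times in set 1 and at 0.296 to 0.520 in set 2, so that WT numbers were taken to mark 1 culture followed over time, which is in doubt for the array labelled untreated WT replicate 1 of set 2 (closing section). In KO (0.685 to 0.811), C61A (0.538 to 0.655), control siRNA (0.310 to 0.759) and Usp18 siRNA (0.412 to 0.526) 2 pairs only hint likewise. Sex-linked genes also part the KO numbers. Across genotypes the correlations were -0.154 to -0.066 in set 1 and -0.561 to 0.331 in set 2, and across siRNAs 0.232 to 0.506. Fits with culture as a block, fixed or random (correlation 0.385 in microglia and 0.359 in BV-2), and with the replicate number within a set as a block were run as alternatives. Further alternatives were set as an additive term, no set term, no filter, a filter at the 75th percentile, quantile normalization again, each array centred on its median, the mean of the probe sets of a gene, a mean-dependent prior variance, leaving out each array, each set alone, a crossed block and leaving out 3 arrays of doubted label or content.

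The tests were tried on simulated data with 100 changed genes of each size. For KO against WT untreated (7960 genes), 51 of 100 genes with a log2 change of 1 and 88 of 100 with a change of 2 were recovered, with 5 false calls. For the Usp18 siRNA against the control siRNA at 24 h (7163 genes), 57 and 91 of 100 were recovered, with 16 false calls, and each recovered gene had the right sign.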

Results

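The 36 arrays fell into 18 groups of 2 replicates. They covered primary mouse microglia that were wild type (WT), Usp18 knockout (KO) or carried the Usp18 C61A point mutation of the catalytic cysteine, and BV-2 microglial cells given a control siRNA or a Usp18 siRNA. Each was left untreated or given 500 U/ml IFN-b for 6 h or 24 h. The WT microglia were deposited in 2 sets, set 1 beside the KO arrays and set 2 beside the C61A arrays, and each mutant was compared with the WT arrays of its own set. Expression in WT arrays correlated at 0.932 to 0.982 within a set and at 0.839 to 0.905 between sets, and 2167, 2459 and 2601 genes differed between the WT arrays of set 1 and set 2 at 0 h, 6 h and 24 h. A gene rose or fell where its adjusted p was under 0.05 (limma, Benjamini-Hochberg). Changes are log2 values with the standard error after the ± sign. Detection calls were not used here, and the lower group lay under the lowest array median (5.594) in 64 of the 167 called changes between groups that are named below, and both groups in 2, so the size of such a change depends on the floor of the array. Of the fixed gene lists, no shift of a whole list held in camera with an estimated correlation (lowest adjusted p = 0.212 in microglia and adjusted p = 0.162 in BV-2), so lists are given by their members.

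Usp18, the interferon-induced ISG15 protease and receptor brake that defines the study, was read by 1 probe set. In KO arrays it lay at 4.40 and 3.77 untreated and at 5.85 to 6.42 after IFN-b. In WT arrays of set 1 it went from 5.68 and 5.99 to between 10.71 and 12.56. Whether this probe set lies in the deleted part of the gene was not given in the sources used here, and for the C61A arrays, whose transcript is intact, it checks nothing. Usp18 was lower in KO than in WT by 6.35 ± 0.906 at 6 h (adjusted p = 0.0023) and by 4.99 ± 0.906 at 24 h (adjusted p = 0.0015), whereas untreated cells did not pass (a change of -1.75 ± 0.906, adjusted p = 0.199). The IFN-b response of Usp18 in KO cells, 2.05 ± 0.906 at 6 h (adjusted p = 0.164) and 1.86 ± 0.906 at 24 h (adjusted p = 0.242), did not pass either. On set 1 arrays only these 3 KO tests passed (adjusted p = 0.0033, 0.0087 and 0.0446), as they did without the doubted arrays of set 2 named below (adjusted p = 0.0155, 0.0101 and 0.0329), and the 6 h response also without either untreated WT array of set 2 (adjusted p = 0.0497). In BV-2 cells Usp18 did not pass between the siRNAs at any time, with changes of -0.02 ± 0.446, -0.29 ± 0.446 and -0.34 ± 0.446 at 0 h, 6 h and 24 h (adjusted p = 1.00, 0.764 and 0.633), so a knockdown of the transcript was not shown. The 6 h value includes an array that carried genes of microglia (below), and without it the change was -0.99 ± 0.391 (adjusted p = 0.460). The sign turned without the untreated Usp18 siRNA replicate 1 (0.52) or the untreated control replicate 2 (0.09) and, at 6 h, without the 6 h Usp18 siRNA replicate 1 (0.40), which leaves only that array in the group.

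**Figure D1:**
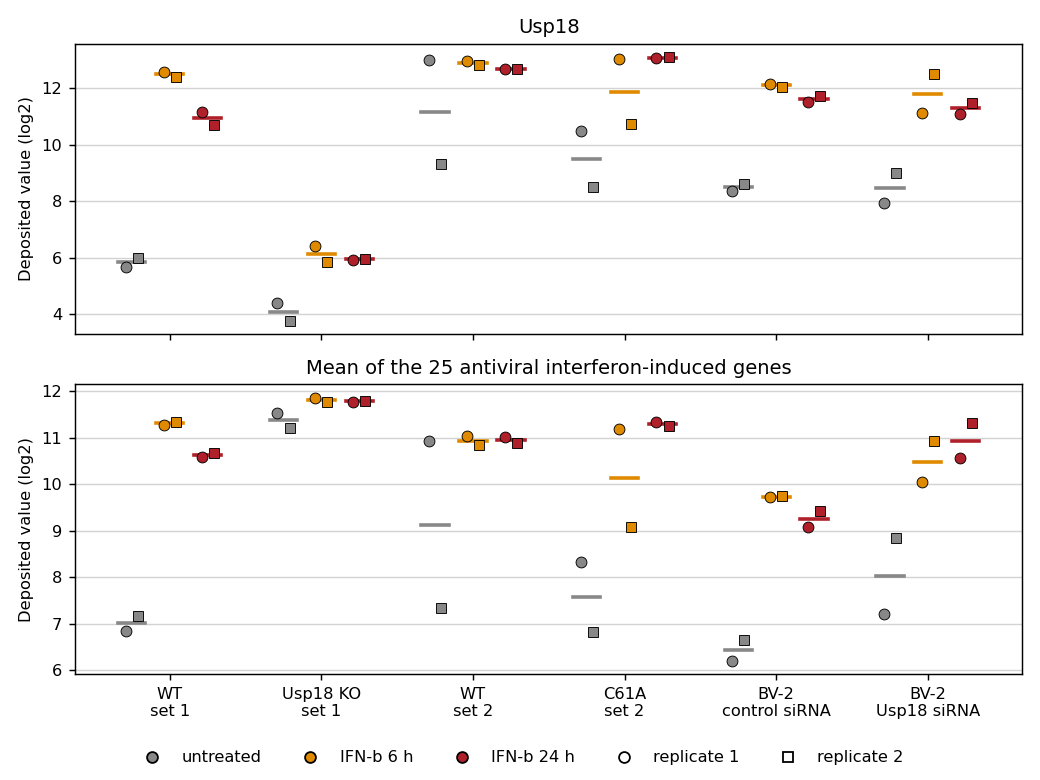
Usp18 (top) and the mean of 25 antiviral genes (bottom) on every array by group, in log2 units, with circles for replicate 1, squares for replicate 2 and bars for group means. The array labelled untreated WT replicate 1 of set 2 stands among the IFN-b-treated arrays, with a Usp18 value of 12.98.

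In set 2 the target and the genes it restrains did not follow every label. The array labelled untreated WT replicate 1 showed Usp18 at 12.98 and a mean of the antiviral genes of 10.93, against 9.31 and 7.34 on the other replicate. Usp18 on the array labelled C61A 6 h replicate 2 was 10.71, against 13.04 on its replicate. That C61A array also carried Ctsk at 12.39 (4.49 to 9.45 on the other arrays of set 2), Mycn at 11.35 (5.38 to 8.20) and Rhox5 at 8.90 (3.48 to 6.33). Among BV-2 arrays, the one labelled Usp18 siRNA 6 h replicate 2 carried the microglial complement gene C1qa at 9.96 (3.54 to 5.10 on the other arrays), Fabp7 at 9.84 (2.58 to 3.31) and Ctsh at 9.75 (2.72 to 3.58). These 3 arrays stayed in the tests under their labels, and values without them are given below as the doubted arrays left out. Directions that rest on the array labelled untreated WT replicate 1 of set 2 hold only if that label is right.

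WT microglia given IFN-b for 6 h raised type I interferon genes of several branches. As means over the sets, some antiviral effectors, interferon-inducible GTPases and chemokines were among the largest increases. Sensors of nucleic acid and class I genes rose as well. The resting microglial receptor Gpr34 and some sterol genes were among those that fell. In all 604 genes rose and 622 fell (668 and 347 with each array centred on its median). Of the antiviral genes 24 of 25 rose (25 of 25 adjusted over the list alone), with a median change of 2.80, among them Isg20, which degrades RNA, by 4.60 ± 0.790. All 9 GTPases rose (9 over the list alone), with Gbp2 up by 4.80 ± 0.694, and so did 13 of 17 chemokines (13 alone), with Ccl12 up by 5.09 ± 0.994 and Cxcl10 by 4.47 ± 0.748. The ISG15 pathway gained its activating enzyme Uba7 (2.00 ± 0.354) along with Usp18 (4.20 ± 0.641, adjusted p = 0.0021), 3 of 4 measured members rising (3 alone). Of the receptor and JAK-STAT genes 7 of 18 rose (7 alone), led by the transcription factor Irf7 (4.17 ± 0.763), and of the nucleic acid sensors 8 of 12 rose (11 rose and 1 fell alone), with Zbp1 at 3.86 ± 0.689 and Dhx58 at 2.82 ± 0.538. Ifi209, a relative of these sensors, rose by 5.01 ± 0.826. For antigen presentation 8 of 13 class I genes rose (11 alone), with the immunoproteasome subunit Psmb9 at 2.14 ± 0.399, but only 1 of 6 class II genes (1 alone). Among 15 inflammatory genes 7 rose (9 alone), with the co-stimulator Cd40 at 3.85 ± 0.543 and the interleukin 1 antagonist Il1rn at 3.09 ± 0.475. Of 15 cell death genes 9 rose (11 rose and 1 fell alone), with the inflammatory caspase Casp4 at 2.17 ± 0.281, and 5 of 15 endoplasmic reticulum stress genes rose (5 rose and 1 fell alone). Complement gained Cfb (2.89 ± 0.556), 1 of 11 genes (1 alone). Gpr34 fell by 2.68 ± 0.329 as the mean over sets, and of 14 resting markers 1 rose and 1 fell (1 and 2 alone). The change was -5.45 in set 1 and 0.09 in set 2 (adjusted p = 0.0011 for the difference), where Gpr34 lay at 2.62 untreated and 2.72 at 6 h. St8sia4, which builds polysialic acid, fell by 2.50 ± 0.210, with -4.17 in set 1 and -0.83 in set 2 (adjusted p = 0.0017). Of 16 cholesterol genes 0 rose and 3 fell (7 fell alone) and none had a positive change, with the sterol carrier Stard4 down by 1.41 ± 0.247. Phagocytic genes (2 of 20 rose, 1 alone) and cell cycle genes (2 of 23 rose, 2 alone) mostly did not pass.

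Among markers of other cells at 6 h in WT, 2 of 5 fibroblast and endothelial genes rose, with the VEGF receptor Kdr at 1.91 ± 0.296. In addition 1 of 9 astrocyte genes fell and 1 of 8 oligodendrocyte genes rose, and 0 of 4 neuron, 0 of 5 border macrophage, 0 of 2 monocyte and granulocyte and 0 of 1 lymphocyte genes passed in limma (unadjusted p under 0.05 for 2618 of all 7960 genes). In sets 1 and 2 Gbp2 rose by 7.96 and 1.64, Cxcl10 by 7.18 and 1.76 and Usp18 by 6.65 and 1.75. None of these set differences passed, but those of 63 genes did. Alone, set 1 gave 1978 genes and set 2, which holds the doubted untreated array, 1. Without that array Usp18 rose by 5.12 over both sets. With arrays of 1 culture paired across times 2632 genes passed, without the doubted arrays 1874, with set as an additive term 619 and with no set term 35. With no set term 13 of the 19 genes named here, Usp18 among them, lost their calls at the same log2 changes (Usp18 4.20, Gbp2 4.80), whereas without any single array all 19 kept them. The count fell to 640 and 557 without the untreated WT replicates 1 and 2 of set 1, 491 without the 6 h replicate 2 of set 1, 364 without the untreated replicate 2 of set 2, and 485 and 746 without the 6 h replicates 1 and 2 of set 2.

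At 24 h of IFN-b 161 genes rose and 45 fell in WT, most class I antigen-processing genes among those that rose. Schlafen and Oas genes and the complement activator Cfb rose as well. Of 13 class I genes 10 rose (13 alone), with Psmb8 at 1.57 ± 0.273 and H2-M3 at 1.56 ± 0.220, and 0 of 6 class II genes passed. Antiviral genes rose in 13 of 25 cases (25 alone), with a median of 2.57 and with Oas3 at 4.32 ± 0.386. Ms4a4c rose by 5.78 ± 1.005, the growth-arrest genes Slfn4 and Slfn1 by 5.24 ± 0.725 and 4.40 ± 0.300, and the chemokine Ccl5 by 4.51 ± 0.427 (3 of 17 chemokines, 10 alone). Irf7 was raised by 4.25 ± 0.763. Of 11 complement genes 3 rose (6 alone), with Cfb at 3.53 ± 0.556, and of 20 phagocytic genes 2 rose (3 alone), with Lgals3bp at 2.35 ± 0.405. The stress factor Ddit3 rose by 2.13 ± 0.285, with 2 of 15 stress genes rising (2 alone). Sorting receptor Sort1 fell by 1.23 ± 0.157 and St8sia4 by 1.32 ± 0.210. Usp18 rose by 3.32 ± 0.641 (adjusted p = 0.0135). The counts of the remaining lists were 3 of 9 GTPases (9 alone), 4 of 12 sensors (7 alone), 2 of 18 signalling genes (3 alone), 2 of 15 cell death genes (7 alone), 0 of 15 inflammatory genes (2 alone), and for the cell cycle 2 of 23 that fell (3 alone).

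Within set 1 alone 175 genes passed at 24 h in WT and within set 2 alone 6, and 0 genes differed between the sets in limma (501 at an unadjusted p under 0.05). Paired by culture the 24 h count was 1338, with the replicate number as a block 410, without the doubted arrays 538, with set as an additive term 121, with no set term 23. Of the 14 genes named here 6 lost their calls with no set term, St8sia4 and Usp18 (adjusted p = 0.0638) also with set as an additive term, all at the same log2 changes (Usp18 3.32). Without the untreated WT replicates 1 and 2 of set 1 the count was 56 and 99, without the 24 h replicates 1 and 2 of set 1 90 and 54, without the untreated replicates 1 and 2 of set 2 427 and 105, and without the 24 h replicate 1 of set 2 59. Usp18 lost its call without the untreated WT replicate 1 of set 1 (3.24, adjusted p = 0.0691), the 24 h replicates 1 and 2 of set 1 (3.21 and 3.43, adjusted p = 0.0560 and 0.0573) or the 24 h replicate 1 of set 2 (3.32, adjusted p = 0.0585).

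Untreated microglia without Usp18 held interferon genes well above untreated WT cells. Antiviral, GTPase, chemokine and antigen presentation genes were raised. Class II genes and the complement genes C2 and Cfb were up as well. Some markers of resting microglia and of border macrophages and some genes of cell division were down, and markers of other cells moved both ways. In all 637 genes rose and 699 fell against WT of set 1. Of the antiviral genes 24 of 25 rose (25 alone), with a median of 3.75, Isg20 at 6.88 ± 1.117 and Oasl1 at 6.46 ± 0.771. All 9 GTPases rose (9 alone), with Gbp2 at 7.34 ± 0.982, and 12 of 17 chemokines rose (12 rose and 1 fell alone), with Cxcl10 at 7.06 ± 1.058 and Ccl5 at 6.44 ± 0.604. Slfn1 rose by 7.08 ± 0.424 (adjusted p = 4.8e-07). Uba7 was raised by 3.22 ± 0.501 (3 of 4 ISG15 genes, 3 alone), Irf7 by 6.47 ± 1.079 (7 of 18 signalling genes, 8 rose and 1 fell alone) and Zbp1 by 5.75 ± 0.975 (7 of 12 sensors, 11 rose and 1 fell alone). In antigen presentation 12 of 13 class I genes rose (13 alone), with Psmb8 at 2.44 ± 0.387, and 4 of 6 class II genes (5 alone), with Cd74 at 2.28 ± 0.410 and H2-Eb1 at 1.53 ± 0.223. Cfb and C2 rose by 4.88 ± 0.786 and 4.26 ± 0.764. Among stress and death genes Ddit3 rose by 3.20 ± 0.403, Atf4 by 1.31 ± 0.195 (4 of 15, 6 alone) and the pore-former Bak1 by 1.77 ± 0.248 (9 of 15, 10 alone). Gpr34 fell by 4.85 ± 0.466 (1 of 14 resting markers rose and 3 fell, 1 and 4 alone), the scavenger receptor Mrc1 by 3.90 ± 0.671 (2 of 5 border macrophage genes, 3 alone), the Wnt inhibitor Dkk2 by 4.75 ± 0.359, the histamine-degrading Hnmt by 3.30 ± 0.441, the protease Adamts1 by 3.23 ± 0.515 and Stard4 by 2.28 ± 0.350. Of 23 cell cycle genes 6 fell (1 rose and 6 fell alone), with Birc5 down by 2.01 ± 0.439. Among markers of other cells Kdr rose by 3.98 ± 0.418 (1 of 5 fibroblast and endothelial genes, 1 alone), Plac8 by 3.52 ± 0.652 (1 of 2 monocyte and granulocyte genes, 1 alone) and Cnp by 1.84 ± 0.443 (1 of 8 oligodendrocyte genes, 1 alone), and the astrocyte gene Glul fell by 2.38 ± 0.664 (1 of 9, 1 alone).

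Without any single array 24 of the 28 called genes named for untreated KO cells kept their calls. Plac8 lost its call without the untreated KO replicate 1 (2.29, adjusted p = 0.0627), and Cnp and Glul theirs without it (1.67 and -1.33) or without the untreated WT replicates 1 (1.89 and -2.67) or 2 (1.79 and -2.09) of set 1. Birc5 was at -1.58 (adjusted p = 0.128) without the untreated KO replicate 1 and -1.89 (adjusted p = 0.0610) without the untreated WT replicate 1 of set 1. The count was 175 without the untreated KO replicate 1, and 476 and 331 without the untreated WT replicates 1 and 2. With set as an additive term 573 genes passed and with no set term, which mixes in the WT arrays of set 2, 245. Of the 28 genes 12 lost their calls with no set term, among them Gbp2, Cxcl10, Mrc1 (-0.59), Gpr34 (-2.09) and Dkk2 (-1.82), and Atf4, Hnmt, Cnp and Glul also lost them with set as an additive term. Of the 5 induced genes chosen in WT of set 2 instead, 4 rose in untreated KO cells, with a median of 2.03.

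After 6 h of IFN-b the antiviral genes of KO and WT cells did not differ past the threshold, and among the genes that did were some inflammatory mediators and resting microglial markers. Interleukin 6 and the prostaglandin synthase Ptgs2 were higher without Usp18. The fractalkine receptor Cx3cr1 and the scavenger receptor Mrc1 were lower. In all 229 genes rose and 433 fell (236 and 265 with quantile normalization again). None of the 25 antiviral genes passed in limma (0 over the list alone; unadjusted p under 0.05 for 1947 of all 7960 genes), with a median of 0.29. Il6 rose by 5.63 ± 1.032, Ptgs2 by 4.0 ± 0.729 and the nitric oxide synthase Nos2 by 2.08 ± 0.365 (4 of 15 inflammatory genes, 4 alone). Aplnr, the apelin receptor, rose by 4.94 ± 0.747, the scaffold Akap12 by 3.72 ± 0.527 and the monocyte gene Plac8 by 4.67 ± 0.652. Cx3cr1 fell by 3.17 ± 0.499 and Fcrls by 1.56 ± 0.285 (1 of 14 resting markers rose and 3 fell, 3 and 5 alone). Mrc1 fell by 4.40 ± 0.671 (1 of 5 border macrophage genes, 3 alone) and the stress gene Herpud1 by 2.08 ± 0.325 (2 of 15 fell). Without the 6 h KO replicate 1 the count was 22 and 9 of the 11 genes named here lost their calls, leaving Plac8 and Usp18. The values without it were 4.84 for Il6 (adjusted p = 0.126), 3.18 for Ptgs2, 1.44 for Nos2, 3.97 for Aplnr, 3.17 for Akap12, -2.84 for Cx3cr1, -1.45 for Fcrls, -3.42 for Mrc1 and -1.71 for Herpud1. Without the 6 h KO replicate 2 the count was 1262, and without the 6 h WT replicates 1 and 2 of set 1 148 and 143, the latter ending the calls of Il6 (5.13, adjusted p = 0.0568), Ptgs2 (3.57) and Fcrls (-1.39). The replicate number as a block gave 1105 genes, the doubted arrays left out 998 and set as an additive term 1285. With no set term the calls of Il6 (3.17), Ptgs2 (1.57) and Mrc1 (-1.03) ended.

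At 24 h 903 genes were higher and 1410 lower in KO than in WT cells. Cytokines, monocyte-attracting chemokines and feedback inhibitors were among the higher ones. Some markers of resting microglia and of border macrophages were lower, as were the lipase Lpl and some sterol genes, and markers of other cells moved both ways. Of 15 inflammatory genes 11 rose (12 alone), with a median of 2.52, among them Il1rn at 5.11 ± 0.672, Il6 at 5.04 ± 1.032 and Ptgs2 at 4.83 ± 0.729. Chemokine genes rose in 5 of 17 cases (6 alone), with Cxcl11 at 6.60 ± 1.075, Ccl7 at 5.10 ± 0.986 and Ccl2 at 4.15 ± 0.744. Of 18 signalling genes 7 rose and 1 fell (7 and 2 alone), with the feedback inhibitor Socs1 at 4.65 ± 0.947, and outside the list Socs2 rose by 5.26 ± 0.437. Aplnr rose by 6.19 ± 0.747. Of 15 cell death genes 7 rose (8 alone), with Casp4 at 2.42 ± 0.398 and Casp1 at 1.63 ± 0.347. Only 1 of 25 antiviral genes rose (0 alone), with a median of 0.88. Cx3cr1 fell by 3.47 ± 0.499, Gpr34 by 3.41 ± 0.466 and Fcrls by 3.36 ± 0.285 (5 of 14 resting markers, 5 alone), Mrc1 by 4.74 ± 0.671 and Stab1 by 3.75 ± 0.697 (2 of 5 border macrophage genes). Lpl fell by 4.81 ± 0.350 (adjusted p = 3.5e-06), the prostaglandin dehydrogenase Hpgd by 6.15 ± 1.325 and Stard4 by 2.02 ± 0.350 (4 of 16 cholesterol genes, 6 alone). Of 23 cell cycle genes 2 rose and 6 fell (3 and 8 alone). Among markers of other cells Plac8 rose by 5.49 ± 0.652 (1 of 2, 1 alone), Kdr by 3.55 ± 0.418 and the endothelial cadherin Cdh5 by 0.96 ± 0.286 (2 of 5, 2 alone), and the astrocyte gene Glul fell by 2.71 ± 0.664 (1 of 9, 1 alone). In WT cells of set 1 Il6 and Ptgs2 lay low, at 2.944 and 2.997, against 7.98 and 7.82 in KO cells. In WT cells of set 2 they lay at 7.81 and 9.80. The sets differ, so this cannot test their excess in KO cells. Without any single array 22 of the 24 genes named here kept their calls. Cdh5 lost its call without the 24 h KO replicate 1 (0.75) or the 24 h WT replicates 1 and 2 of set 1 (1.05 and 0.86), and Glul without the 24 h KO replicate 1 (-2.54) or the 24 h WT replicate 1 (-2.66, adjusted p = 0.0521). The count was 1011 and 1481 without the 24 h KO replicates 1 and 2 and 1068 and 1220 without the 24 h WT replicates 1 and 2 of set 1. With no set term 1505 genes passed and 10 of the 24 lost their calls, namely Ccl7, Ccl2, Il6 (2.60), Ptgs2 (1.43), Casp1, Mrc1 (-1.97), Stab1, Gpr34 (-1.78), Stard4 and Hpgd (-2.05).

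**Figure D2:**
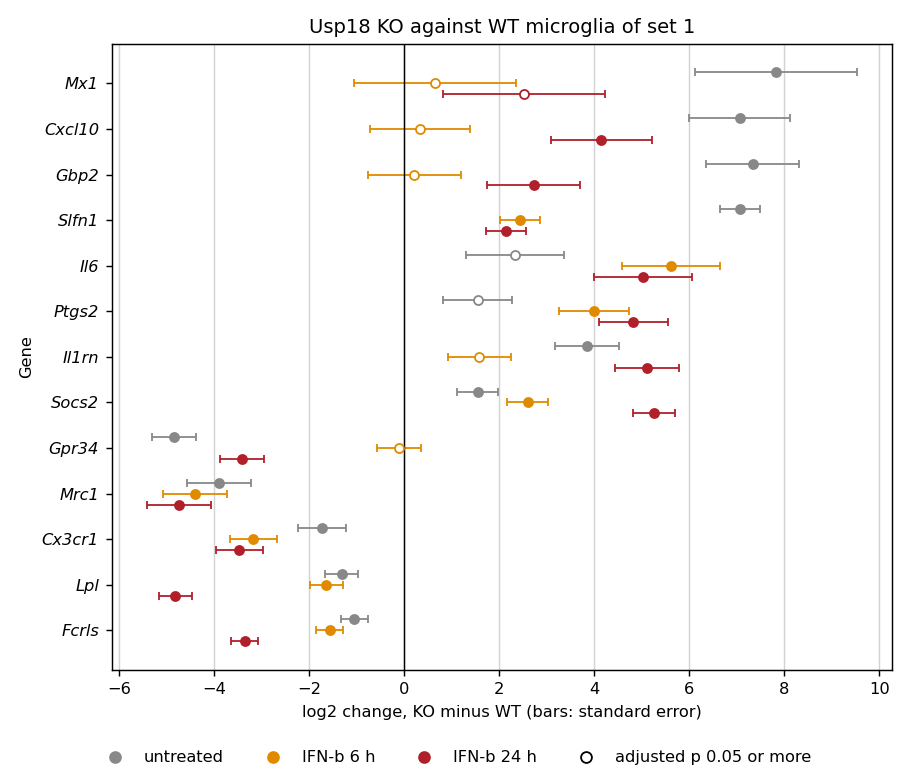
Log2 change of KO against WT of set 1 at 0 h, 6 h and 24 h of IFN-b for 13 genes, with bars of 1 standard error and open symbols where the adjusted p was 0.05 or more. Gbp2 stood at 7.34 untreated and 0.22 at 6 h, and Il6 and Ptgs2 passed only after IFN-b.

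In KO microglia given IFN-b few interferon genes passed, and some inflammatory mediators rose. At 6 h 230 genes rose and 443 fell (181 and 274 with median centring), and at 24 h 138 rose and 178 fell (102 and 116). None of the 25 antiviral genes passed at 6 h (median 0.43) or 24 h (median 0.35) in limma, and 0 did over the list alone (unadjusted p under 0.05 for 2099 and 1765 of all 7960 genes). At 6 h Il6 rose by 4.72 ± 1.032 and Ptgs2 by 3.86 ± 0.729 (4 of 15 inflammatory genes, 8 alone), the feedback inhibitor Socs3 by 3.60 ± 0.739 (3 of 18 signalling genes), the interleukin 12 receptor Il12rb1 by 2.73 ± 0.333 and Spsb1 by 2.55 ± 0.356. Cx3cr1 fell by 2.61 ± 0.499 (2 of 14 resting markers) and the mitochondrial polymerase Polrmt by 1.96 ± 0.264, or 1.18 by the mean of its probe sets. At 24 h Socs2 rose by 2.68 ± 0.437 (2 of 15 inflammatory genes also rose, 3 alone). Lpl fell by 3.74 ± 0.350, the microglial receptor Fcrls by 2.51 ± 0.285 (3 of 14 resting markers, 3 alone) and Tmem176b by 2.48 ± 0.328.

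The 6 h response of KO cells came to 30 genes without the 6 h KO replicate 1, 1175 without the 6 h KO replicate 2 and 12 without the untreated KO replicate 2. Il6 (3.93 and 3.25), Ptgs2 (3.04 and 2.53), Socs3 (2.45 and 3.34) and Cx3cr1 (-2.28 and -2.52) lost their calls without the 6 h KO replicate 1 and without the untreated KO replicate 2. The 24 h response came to 681 and 3 genes without the untreated KO replicates 1 and 2, 30 and 7 without the 24 h KO replicates 1 and 2, 579 without either 6 h KO array, 203 without either untreated WT array of set 1 and 209 without either 24 h WT array of set 1. Socs2 lost its call without the untreated KO replicate 2 (2.12) or either 24 h KO replicate (2.62 and 2.74), and Tmem176b without the untreated KO replicate 2 (-2.12). At 6 h other settings gave 446 genes (set additive), 70 (no set term), 1215 (replicate number as a block), 1818 (culture as a block) and 1209 (doubted arrays left out). At 24 h they gave 29 (no set term), 679 (replicate number as a block), 1413 (culture as a block), 509 (doubted arrays left out) and 40 (set 1 arrays only). With no set term Il6, Ptgs2, Socs3, Spsb1 and, at 24 h, Fcrls (adjusted p = 0.0537) lost their calls.

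Tested against the WT response of set 1, the response of KO cells was smaller for some interferon genes. Fewer genes differed upward than downward. Untreated KO cells held many of these interferon genes high already (Slfn1 by 7.08 and Ccl5 by 6.44 over WT). The smaller response therefore cannot be separated from the untreated difference. At 6 h 23 genes differed upward and 68 downward, and at 24 h 17 and 40. At 6 h the response fell short for the itaconate enzyme Acod1 by 6.12 ± 0.567, Ccl5 by 5.64 ± 0.855, Slfn1 by 4.63 ± 0.599, the immunomodulator Fgl2 by 4.28 ± 0.673 and Atf4 by 1.76 ± 0.275. Upward stood St8sia4 (2.65 ± 0.419) and the co-chaperone Dnajc12 (2.55 ± 0.317). Gpr34 (4.75 ± 0.659, 1 of 14 resting markers, 1 up and 1 down alone) and Dkk2 (4.44 ± 0.508) also passed, but both lay low in untreated KO cells (3.29 and 3.85, against 8.14 and 8.59 in WT of set 1), where a further fall could not be read. At 6 h 3 of 25 antiviral genes had a smaller response (20 alone, median -3.27), as had 1 of 9 GTPases (9 alone), 3 of 17 chemokines (10 alone) and 3 of 15 stress genes (5 alone). At 24 h 1 of 25 antiviral genes did (13 alone, median -2.90), 0 of 9 GTPases (2 alone) and 1 of 17 chemokines (3 alone), with Oas3 at -5.70 ± 0.771 and Slfn1 at -4.93 ± 0.599. Lpl at -3.50 ± 0.495 and the resting marker Fcrls at -2.31 ± 0.403 (1 of 14, 2 alone) fell in KO cells beyond WT. With set as an additive term 2 genes differed at 6 h and 44 at 24 h, and with no set term 1 and 9. Both ended the 6 h calls of all 9 named genes but Dnajc12 and the 24 h calls of Slfn1 and Oas3, no set term also ended that of Fcrls (-2.49), and Atf4 lost its call by the mean of its probe sets (adjusted p = 0.0681). Paired by culture 467 and 534 genes differed at 6 h and 24 h, with the replicate number as a block 231 and 125, with set 1 arrays only 275 and 157, without the doubted arrays 362 and 208, without the filter 50 at 6 h and with each array centred on its median 39 and 37.

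All 9 genes named for the 6 h difference of the KO response kept their calls without any single array, and of the 4 named at 24 h Slfn1 did. Fcrls lost its call without the untreated KO replicate 1 (-2.19), the 24 h KO replicate 2 (-1.79), the untreated WT replicates 1 and 2 of set 1 (-2.47 and -2.16) or the 24 h ones (-2.12 and -2.50). Lpl (-3.39) and Oas3 (-5.23) missed narrowly without the 24 h WT replicate 2 of set 1 (adjusted p = 0.0517). The 6 h count was 25 without the untreated KO replicate 1, 24 without the 6 h KO replicate 1, 30 and 24 without the untreated WT replicates 1 and 2 of set 1, 54 and 27 without the 6 h WT replicates 1 and 2 of set 1, 44 without either 24 h KO array, 49 without either 24 h WT array of set 1, 203 without either untreated WT array of set 2, 41 without either 6 h and 43 without either 24 h WT array of set 2, 47 without either untreated and 56 without either 24 h C61A array. At 24 h it was 24 without the untreated KO replicate 2, 21 and 10 without the 24 h KO replicates 1 and 2, 15 and 5 without the untreated and 8 and 2 without the 24 h WT replicates 1 and 2 of set 1, and 94 without either untreated WT array of set 2.

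C61A microglia, whose Usp18 protein lacks its catalytic cysteine, raised the interferon program with IFN-b. At 24 h 435 genes rose and 289 fell, and at 6 h 4 genes passed, all of them upward. In the antiviral list 22 of 25 genes rose at 24 h (25 alone), with a median of 3.42 and Oasl1 at 5.46 ± 0.771. Slfn4 rose by 7.40 ± 1.026. All 9 GTPases, 4 of 4 ISG15 genes (4 alone), 9 of 18 signalling genes (12 alone), 6 of 12 sensors (8 alone) and 9 of 17 chemokines (11 alone) rose, with Ccl5 at 4.85 ± 0.604. Usp18 itself rose by 3.58 ± 0.906 (adjusted p = 0.0263). Of 13 class I genes 12 rose (13 alone), with H2-M3 at 2.59 ± 0.311. Of 11 complement genes 6 rose (6 alone), with C1qc at 0.88 ± 0.139, and of 15 cell death genes 6 (6 alone), with Casp4 at 2.83 ± 0.398. Of 15 inflammatory genes 7 rose (13 rose and 1 fell alone). Tmem119, a marker of resting microglia, fell by 3.32 ± 0.585 and the growth factor receptor Csf1r by 1.65 ± 0.274 (1 of 14 rose and 3 fell, 1 and 4 alone), Hnmt by 2.70 ± 0.441 and Etl4 by 2.60 ± 0.378. Without any single array 9 of the 11 genes named at 24 h kept their calls. Usp18 lost it without the untreated C61A replicate 2 (2.60, adjusted p = 0.180) or the 24 h replicates 1 and 2 (3.60 and 3.56), and Tmem119 without the 24 h replicate 1 (-3.37, adjusted p = 0.0541). The 24 h count was 182 and 155 without the untreated C61A replicates 1 and 2 and 63 and 105 without the 24 h replicates 1 and 2. It was 467 with set as an additive term, 43 with no set term, 1110 with the replicate number and 1842 with culture as a block, and 190 on set 2 arrays only. With no set term 7 of the 11 lost their calls (Usp18, Casp4, C1qc, Csf1r, Hnmt, Etl4 and Tmem119), on set 2 arrays only Usp18, Hnmt and Tmem119, and with set as an additive term Usp18. The log2 changes were the same with no set term and with the additive term (Usp18 3.58).

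The 4 genes that rose in C61A cells at 6 h were the protease Ctsk (6.30 ± 0.710), Mycn (4.30 ± 0.654), Rhox5 (3.79 ± 0.609) and Ly86 (1.30 ± 0.190). Of the 2 other probe sets of Mycn 0 went the same way. Ctsk, Mycn and Rhox5 are the genes that stood out on the array labelled C61A 6 h replicate 2. Ctsk and Rhox5 lay at 12.39 and 8.90 there. They were next highest in set 2 on the other 6 h C61A array (9.45 and 6.33). Ctsk also stood at 8.11 on the 6 h WT replicate 1. In the antiviral list 0 of 25 genes passed in limma (466 of all 7960 genes at an unadjusted p under 0.05) but 23 did over the list alone, with a median of 2.37, as did 7 of 9 GTPases, 11 of 17 chemokines and 4 of 4 ISG15 genes. Usp18 changed by 2.38 ± 0.906 and did not pass (adjusted p = 0.809), and by 3.54 (adjusted p = 0.0013) without the doubted arrays. Without those 414 genes passed at 6 h, on set 2 arrays only 0 (all 4 losing their calls), with the replicate number as a block 9 and with culture as a block 45. The count was 26 without either untreated WT array of set 2, 11 without the 6 h C61A replicate 1, 1 and 0 without the untreated C61A replicates 1 and 2, 2 without either 6 h KO or untreated WT array of set 1, and 1 without either 24 h KO, 24 h WT of set 1, 6 h WT of set 1, 24 h WT of set 2 or 24 h C61A array. Mycn and Rhox5 lost their calls in each of these pairs of KO, WT of set 1, 24 h WT of set 2 and C61A arrays (adjusted p = 0.0538 and 0.0627 without either 24 h KO array). Ly86 lost it there too except without the 6 h KO or untreated WT arrays, and also without the 6 h C61A replicate 1 (1.03). Without the untreated C61A replicates 1 and 2 the values were 4.20 and 4.40 (Mycn), 3.70 and 3.87 (Rhox5) and 1.19 and 1.41 (Ly86), and they did not move without arrays of other groups. Ctsk lost it without the untreated C61A replicate 2 (6.18, adjusted p = 0.0687) and Rhox5 without the 6 h C61A replicate 2 (2.50, adjusted p = 0.0916). Rhox5 also missed with the replicate number as a block, quantile normalization again and median centring (adjusted p = 0.0544, 0.0518 and 0.0530), and Ly86 with no set term (adjusted p = 0.237).

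Few genes told C61A and WT microglia of set 2 apart. Only Ly86, a partner of a Toll-like receptor relative, was lower untreated (-1.51 ± 0.190), LOC664787 at 6 h (-2.56 ± 0.343) and at 24 h (-2.52 ± 0.343), and Rasgrf1, an exchange factor for Ras, at 24 h (-1.52 ± 0.221). Unadjusted p lay under 0.05 for 391, 252 and 578 genes at 0 h, 6 h and 24 h. No antiviral gene passed in limma (0 over the list alone), with medians of -1.75, -0.77 and 0.34, and none of the 9 astrocyte markers did (0 alone), with medians of 0.28, 0.29 and 0.82. The cultures differed in such markers. Aqp4 lay at 3.08 and 3.52 on the WT replicate 1 arrays at 6 h and 24 h, 10.36 and 9.77 on those of replicate 2 and 10.90 and 8.39 on the C61A arrays at 24 h. The untreated and 6 h medians lean on the array labelled untreated WT replicate 1 and the array labelled C61A 6 h replicate 2. Usp18 changed by -1.65 ± 0.906, -1.01 ± 0.906 and 0.40 ± 0.906 (adjusted p = 1.00, 0.998 and 0.943), and without the doubted arrays, the array labelled untreated WT replicate 1 and the array labelled C61A 6 h replicate 2, by 0.19 and 0.15 at 0 h and 6 h. Without the untreated WT replicate 2 of set 2 it was lower untreated by 3.48 (adjusted p = 0.0319), a direction that rests on the array labelled untreated WT replicate 1. The IFN-b response of C61A cells differed from WT for 0 genes at 6 h and 0 at 24 h in limma (26 and 497 at an unadjusted p under 0.05). Without the doubted arrays 3, 4 and 99 genes differed between C61A and WT at 0 h, 6 h and 24 h, on set 2 arrays only 0 at each time, with the replicate number as a block 1, 2 and 29. With set as an additive term 1, 6 and 6 did, and with no set term 1, 5 and 0. Ly86 lost its call without the array labelled untreated WT replicate 1 of set 2 (-1.27) or the untreated C61A replicate 1 (-1.40), the counts then being 0, while they were 170 without the untreated WT replicate 2 of set 2 and 2 without the untreated C61A replicate 2. LOC664787 lost its 6 h call without either WT (-2.63 and -2.49, 0 genes) or either C61A 6 h replicate (-2.30 and -2.81, 6 and 0 genes), with 2 genes without either untreated C61A array. At 24 h LOC664787 lost it without the WT replicates 1 and 2 (-2.79 and -2.26, 0 and 1 genes) or the C61A replicate 1 (-2.04, 0 genes), and with no set term (adjusted p = 0.0539). Rasgrf1 lost it without the WT replicate 1 (-1.18) or the C61A replicates 1 and 2 (-1.45 and -1.60, 0 and 1 genes), with set additive or no set term (-0.11), with median centring and with the trended prior. Counts at 24 h were 8 without either untreated WT array and 21 without either 6 h C61A array. The differing response came to 4 genes at 6 h without the 6 h C61A replicate 1 and to 83 at 24 h without the untreated WT replicate 2 of set 2.

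Loss of Usp18 and loss of its catalytic cysteine, each against its own WT, were compared directly. In untreated cells the KO effect exceeded the C61A effect for 601 genes and fell below it for 370, with interferon genes among the former. At 6 h 34 and 31 genes differed and at 24 h 158 and 89. Untreated, 23 of 25 antiviral genes stood higher with the knockout (25 alone), with a median of 5.37 and Oasl1 at 9.07 ± 1.091. The same held for 9 of 9 GTPases (median 7.74), 11 of 17 chemokines (13 alone), with Ccl5 at 7.81 ± 0.855, and 10 of 13 class I genes (12 alone). The transcription factors Irf7 and Stat2 stood at 8.27 ± 1.526 and 6.05 ± 1.249, Uba7 at 4.06 ± 0.708 and the class II gene H2-Eb1 at 1.59 ± 0.315. Cell death genes did so in 8 of 15 cases (9 alone), with Daxx at 5.27 ± 0.985, Casp4 at 3.77 ± 0.562 and Bak1 at 2.64 ± 0.351. Lower were Hnmt (-3.77 ± 0.624), Stard4 (-2.50 ± 0.495) and the mitotic kinase Bub1 (-2.80 ± 0.551), with 7 of 23 cell cycle genes (13 alone). At 6 h 0 of 25 antiviral genes passed in limma (0 alone, median 1.20; 1411 of all 7960 genes at an unadjusted p under 0.05), and LOC664787 stood at 3.72 ± 0.485. At 24 h 0 of 25 passed again (0 alone, median 0.61; 1678 genes), and Sectm1a (6.20 ± 0.996), Plac8 (5.23 ± 0.922) and LOC664787 (4.70 ± 0.485) stood higher, Lpl (-3.68 ± 0.495), Fcrls (-3.27 ± 0.403), Smagp (-2.72 ± 0.389) and Usp18 (-5.38 ± 1.281, adjusted p = 0.0371) lower. Because the array labelled untreated WT replicate 1 of set 2 enters the untreated test as a control, the size of the difference rests in part on its label. Without that array the antiviral median was 3.50 (14 of 25 passing) and that of the GTPases 5.48 (8 of 9), with Oasl1 at 7.21, Irf7 at 5.89, Stat2 at 4.05 and Daxx at 3.68. Then 8 of 17 chemokines and 5 of 13 class I genes passed. Without both doubted arrays of set 2 21 of 25 antiviral genes did. Without the doubted arrays 534, 9 and 520 genes differed at 0 h, 6 h and 24 h.

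All 12 genes named for the untreated difference of KO and C61A effects kept their calls without any single array, with counts of 256 without the untreated KO replicate 1, 454 and 385 without the untreated WT replicates 1 and 2 of set 1, 286 without the array labelled untreated WT replicate 1 of set 2 and 420 without the untreated C61A replicate 1. With set as an additive term 471, 1638 and 578 genes differed at 0 h, 6 h and 24 h and with no set term 1089, 2215 and 1000. These 2 settings lowered Ccl5 to 4.80 and 4.71, the first ended the calls of Hnmt (-1.83) and, at 24 h, Usp18 (adjusted p = 0.0542), and the second ended those of Bub1, Stard4 and, at 24 h, Smagp (-0.35), and lowered Bak1 to 1.70. The replicate number as a block gave 241 and 623 genes at 6 h and 24 h, median centring 10 and 158, and at 6 h no filter gave 19, the stricter filter 8, quantile normalization again 22, the trended prior 15 and the mean of probe sets 111. The 6 h count was 0 and 611 without the 6 h KO replicates 1 and 2, 5 and 11 without the 6 h WT replicates 1 and 2 of set 1, 2 and 0 without those of set 2, 361 and 2 without the 6 h C61A replicates 1 and 2, 20 without either untreated C61A array and 2 without either 24 h KO, untreated WT of set 1, 24 h WT of set 1, 24 h WT of set 2 or 24 h C61A array. LOC664787 missed at 6 h without the 6 h KO replicate 1 (3.55, adjusted p = 0.0700) or the 6 h WT replicate 2 of set 2 (3.65, adjusted p = 0.0637). The 24 h count was 65 and 49 without the 24 h KO replicates 1 and 2, 42 and 64 without the 24 h WT replicates 1 and 2 of set 1, 61 and 63 without those of set 2, 72 without either 24 h C61A array, 408 without either untreated and 414 without either 6 h KO array, and 153 without either untreated WT array of set 1. Usp18 lost its call at 24 h without either 24 h KO (-5.36 and -5.41), either 24 h C61A (-5.40 and -5.37), either 24 h WT of set 1 (-5.16 and -5.60) or set 2 (-5.37 and -5.39), either untreated WT of set 1 or either 6 h WT of set 2 (-5.38).

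BV-2 cells with the control siRNA raised antiviral genes, GTPases and sensors with IFN-b. At 6 h 71 genes rose and at 24 h 36, and none fell. At 6 h 18 of 25 antiviral genes rose (24 alone), with a median of 2.75, and 8 of 9 GTPases (9 alone), with Gbp7 at 5.24 ± 0.453. Cxcl10 rose by 6.40 ± 0.415 (1 of 13 chemokines, 1 alone), the sensors Ifi204 and Dhx58 by 3.96 ± 0.367 and 2.97 ± 0.293 (5 of 10, 6 alone), and the inflammasome cytokine Il18 by 2.56 ± 0.203 (2 of 17 inflammatory genes, 7 alone). Of 13 class I genes 2 rose (9 alone). Usp18 rose by 3.61 ± 0.446 (adjusted p = 0.0092). At 24 h 12 of 25 antiviral genes rose (21 alone), with a median of 2.36, and 4 of 9 GTPases (9 alone), with Gbp3 at 4.32 ± 0.512 and Gbp6 at 3.39 ± 0.345. Ifi204 was raised by 3.77 ± 0.367 and Usp18 by 3.13 ± 0.446 (adjusted p = 0.0209). Each of the genes named at 6 h but Usp18 kept its call without any single array. The 6 h count was 9 and 13 without the untreated control replicates 1 and 2, 9 and 8 without the 6 h replicates 1 and 2 and 32 without either 24 h replicate, and Usp18 lost its call without the untreated (3.50 and 3.72) or 6 h replicates (3.55 and 3.66). The 24 h count was 2 and 8 without the untreated control replicates, 19 without either 6 h and 1 without either 24 h replicate. At 24 h Gbp3, Gbp6 and Ifi204 lost their calls without the untreated replicate 1 (3.79, 3.13 and 3.51), the 24 h replicate 1 (4.60, 3.55 and 3.93) or the 24 h replicate 2 (4.03, 3.23 and 3.62), and Usp18 without any control array (3.03 and 3.24 untreated, 3.13 at 6 h, 3.25 and 3.02 at 24 h). With the replicate number as a block 119 and 107 genes passed at 6 h and 24 h, and with culture as a block 132 and 135.

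BV-2 cells given the Usp18 siRNA kept responding up to 24 h. At that time interferon, inflammatory and antigen presentation genes were high and cell division genes low. At 6 h 73 genes rose and 68 fell, and at 24 h 474 rose and 662 fell. With quantile normalization again the counts were 86 and 29 at 6 h and 513 and 442 at 24 h. With median centring they were 71 and 26, and 494 and 430. The excess of falling genes at 24 h rests on the scale of the deposited values. Of the antiviral genes 8 of 25 rose at 6 h (23 alone), with a median of 2.25, and 24 of 25 at 24 h (25 alone), with a median of 2.62. Cxcl10 rose by 6.20 ± 0.415 and 6.50 ± 0.415 at 6 h and 24 h and Gbp2 by 5.65 ± 0.688 and 6.12 ± 0.688 (7 and 9 of 9 GTPases). Irf1, a driver of inflammatory interferon genes, rose by 2.58 ± 0.288 and 3.47 ± 0.288, and Usp18 by 3.34 ± 0.446 (adjusted p = 0.0168) and 2.82 ± 0.446 (adjusted p = 0.0075). Il18 rose by 2.17 ± 0.203 at 6 h (4 of 17 inflammatory genes, 6 alone). At 24 h 9 of 17 inflammatory genes rose (11 alone), with Cd40 at 3.75 ± 0.482, Il15 at 3.09 ± 0.296 and Cd86 at 3.03 ± 0.273. Of 13 chemokines 5 rose (9 alone), with Cxcl11 at 5.87 ± 0.631, and of 13 class I genes 12 (12 alone), with Psmb9 at 2.04 ± 0.235 and the peptide transporter Tap2 at 1.97 ± 0.157. The endosomal sensor Tlr3 rose by 4.48 ± 0.546, and 6 of 13 cell death genes rose (6 alone), with Daxx at 3.14 ± 0.318, Casp4 at 2.70 ± 0.297 and the death receptor Fas at 1.79 ± 0.218. Of 24 cell cycle genes 17 fell (20 alone), with a median of -1.25 and Plk1 at -2.06 ± 0.319, and 7 of 16 cholesterol genes fell (8 alone), with Idi1 at -1.63 ± 0.244.

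The 6 h response under the Usp18 siRNA leaned on the doubted array: without that array, labelled Usp18 siRNA 6 h replicate 2, 3 genes passed and Gbp2 (5.26), Irf1 (2.40) and Usp18 (2.64, adjusted p = 0.0820) lost their calls. The untreated replicate 1 carried it as well, with 3 genes without it and lost calls for Il18 (2.05), Irf1 (2.38) and Usp18 (2.80). Other 6 h counts were 46 without the untreated replicate 2, 836 without the 6 h replicate 1, 529 without either 24 h replicate, and 39, 30 and 33 without either untreated, 6 h or 24 h control array. At 24 h the counts were 55 and 218 without the untreated and 2176 and 129 without the 24 h replicates 1 and 2, and 739 and 714 without either 6 h or 24 h control array. Of the 16 genes named at 24 h 13 kept their calls throughout. Idi1 (-1.61), Plk1 (-2.14) and Usp18 (2.28) lost theirs without the untreated replicate 1, and Plk1 (-1.84) and Usp18 (2.61) without the 24 h replicate 2. With the replicate number as a block 746 and 2051 genes passed at 6 h and 24 h, with culture as a block 1061 and 2277, and without the filter 78 at 6 h.

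Against the control siRNA, the Usp18 siRNA raised interferon and inflammatory genes at 24 h of IFN-b, with 220 genes higher and 163 lower. Cytokines and chemokines led. Some cell division and sterol genes were lower. Of 17 inflammatory genes 8 rose (14 alone), with a median of 2.05, among them Il6 at 5.91 ± 0.907 and Cd40 at 3.55 ± 0.482. Of 13 chemokines 5 rose (10 alone), with Cxcl11 at 5.96 ± 0.631 and Cxcl10 at 5.22 ± 0.415. Of the antiviral genes 6 of 25 rose (14 alone), with a median of 1.34, and 4 of 9 GTPases (9 alone). Irf1 rose by 2.76 ± 0.288 (3 of 18 signalling genes, 9 alone), Tap2 by 1.75 ± 0.157 (3 of 13 class I genes, 11 alone), Daxx by 2.66 ± 0.318 and the coagulation factor F8 by 4.43 ± 0.349. Of 16 cholesterol genes 4 fell (10 alone), with Idi1 at -1.56 ± 0.244 and Msmo1 at -1.33 ± 0.231, and of 24 cell cycle genes 5 (1 rose and 17 fell alone). Of 284 genes induced by IFN-b in WT microglia 83 rose and 0 fell, with a median of 1.23. Untreated and at 6 h 0 genes passed in limma (176 and 1007 at an unadjusted p under 0.05). Over the lists alone 19 of 25 antiviral genes (median 1.39) and 4 of 9 GTPases rose untreated, and 14 of 24 cell cycle and 11 of 16 cholesterol genes fell at 6 h. Without the 6 h array that carried genes of microglia 0 of 24 cell cycle genes (median -0.64 against -0.84) and 10 of 16 cholesterol genes (median -0.86 against -0.85) fell over the lists alone. The response itself differed between the siRNAs for 0 genes at 6 h in limma (244 at an unadjusted p under 0.05) and at 24 h for 2, F8 (4.18 ± 0.493) and the cytokine-like Fam3b (3.24 ± 0.246), both larger with the Usp18 siRNA.

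**Figure D3:**
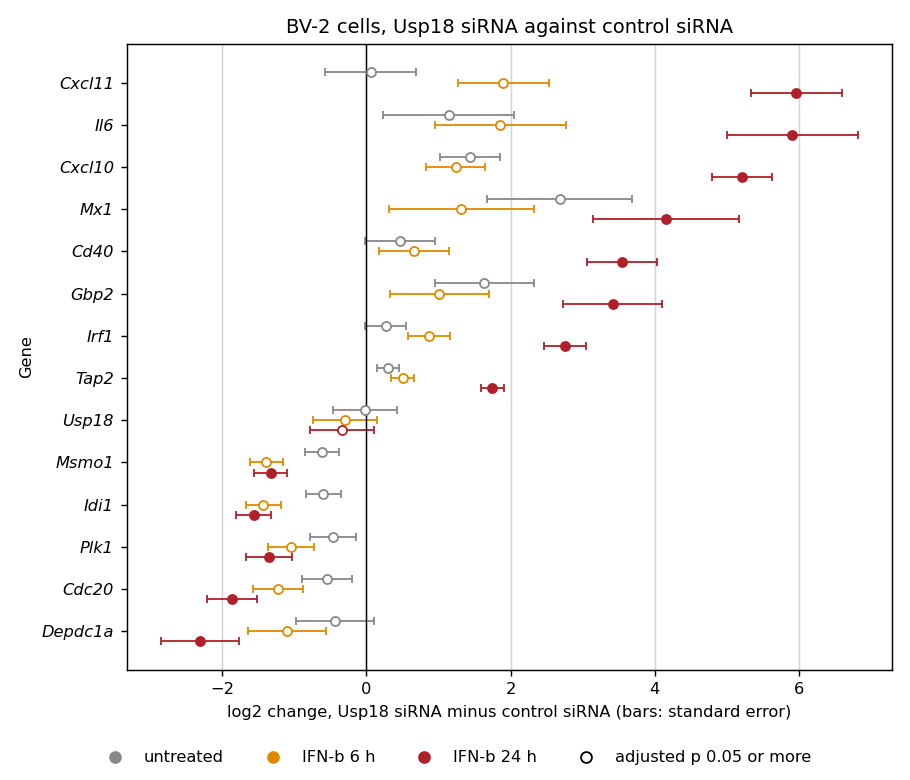
Log2 change of Usp18 siRNA against control siRNA in BV-2 cells at 0 h, 6 h and 24 h of IFN-b for 14 genes, with bars of 1 standard error and open symbols where the adjusted p was 0.05 or more. Cxcl11 (5.96) and Il6 (5.91) stood highest at 24 h, and Usp18 passed at no time.

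The count at 24 h between the siRNAs turned on single arrays: 1927 and 23 without the 24 h Usp18 siRNA replicates 1 and 2, 5 and 12 without the 24 h control replicates 1 and 2, 129 and 655 without either untreated or either 6 h Usp18 siRNA array, and 108 and 78 without either untreated or 6 h control array. Cxcl10, F8 and Tap2 kept their calls throughout. Cxcl11 (5.69), Irf1 (2.62), Cd40 (3.35), Daxx (2.58), Idi1 (-1.75), Msmo1 (-1.66) and Il6 (5.50) lost theirs without the 24 h control replicate 1. Without the 24 h control replicate 2 Cd40 (3.75), Daxx (2.74), Idi1 (-1.38), Msmo1 (-1.0) and Il6 (6.32) did, and without the 24 h Usp18 siRNA replicate 2 Idi1 (-1.21), Msmo1 (-1.24) and Il6 (4.65). Untreated 4 genes passed without the untreated Usp18 siRNA replicate 1 and 3 with the replicate number as a block, and at 6 h 293 without the 6 h Usp18 siRNA replicate 1. The replicate number as a block gave 1456 genes at 24 h, no filter 161 and the doubted array left out 655. For the differing response at 24 h F8 lost its call without the untreated (3.93 and 4.43) or the 24 h replicate 2 (3.66) of the Usp18 siRNA and without any control array (4.08 and 4.28 untreated, 4.18 at 6 h, 4.05 and 4.31 at 24 h), with no filter, the stricter filter, quantile normalization again and the crossed block, and F8 and Fam3b (adjusted p = 0.0611) with the trended prior. The count was then 1 without the untreated Usp18 siRNA replicate 1, the 24 h Usp18 siRNA replicate 2 or any control array, 5 without either 6 h and 353 without the 24 h Usp18 siRNA replicate 1, and 16 with the replicate number and 29 with culture as a block. At 6 h it was 1 and 32 without the untreated and the 6 h Usp18 siRNA replicate 1.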

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

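Of the tests in this part, those on the array labels, on RNA of the other cell system and on the rank of Usp18 were chosen after the result was seen, and the splits of the WT arrays were chosen before. Among the untreated WT arrays 1 array, labelled replicate 1 of set 2, stood apart from the other 3 in Mx1 (gap of 0.852 of the range) and in the mean of the antiviral genes (0.881), where 15 tests were run, 5 measures in each of the 3 WT groups of 4 arrays, and chance alone would single out an array in about 1 in 20 tests. An exchange with the array labelled C61A 6 h replicate 2 is a candidate explanation. It was checked over 500 of 2901 genes that did not respond to IFN-b in set 1. These 500 were the genes that varied most between cultures on the 10 other arrays of set 2. The array labelled untreated WT replicate 1 correlated at 0.649 with the cultures labelled C61A replicate 2. The array labelled C61A 6 h replicate 2 correlated at 0.830 with the cultures labelled WT replicate 1 against 0.218 with its own. Against interferon or activation in the labelled culture, the array correlated at 0.168 with that culture, below the 0.301 to 0.856 of the 10 other arrays of set 2, each of which matched its own culture best. The exchange remains a hypothesis, since both arrays were picked out by the same data.

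On 2 arrays genes of the other cell system appeared. The markers were chosen as genes more than 3 log2 units apart between the BV-2 and set 2 arrays, with these 2 arrays left out. Low values on the other arrays were therefore largely fixed by that choice. On the BV-2 array labelled Usp18 siRNA 6 h replicate 2, 83 microglia markers stood at a median of 46.31% of their microglia level (quartiles 34.16% to 59.37%, 83 of 83 above 5%), against at most 0.08689% on the 11 other BV-2 arrays. On the array labelled C61A 6 h replicate 2, 22 BV-2 markers stood at 12.67% of their BV-2 level (22 of 22 above 5%), against at most 0.5505% on the 11 other arrays of set 2. RNA of the other system on each array may account for this, by mixing before or during labelling. A change of cell state under the Usp18 siRNA and IFN-b could not be tested by the other replicate of the group. The microglia markers stood at 0.04408% there, but that array was among those on which they were chosen to be low.

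In BV-2 cells interferon genes were higher with the Usp18 siRNA at 24 h while Usp18 itself was hardly lower. Among 283 genes induced by IFN-b in WT microglia, with a median change of 1.23, 1 gene, or 0.3534%, lay lower than Usp18 at -0.34 ± 0.446. The lowest 5% of these genes ended at 0.19, less than 2 standard errors above Usp18, and a low rank was already part of the pattern. A transcript held down by the siRNA against a raised interferon tone and a general interferon response to the siRNA that leaves Usp18 alone therefore cannot be told apart by this rank. Whether the siRNA raises these genes through Usp18 or through another route was not tested, since the array gives no protein level.

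For the WT response at 6 h, fitted without sets, 4 of the 35 splits of the 8 arrays gave as many genes as the real split (589), the highest of the others being 3029 for the split that follows the sets, which points to a structure of the samples by set. Chance was therefore not excluded by the splits. The other 2 splits (806 and 1498 genes) put the array labelled untreated WT replicate 1 of set 2 with the 6 h arrays. Of the 8 splits that part every pair of a culture, the highest other gave 806. At 24 h 2 of 35 splits gave as many as the real split (192), the other being the split along the sets (3572), so that chance was not excluded by the share of all splits, and the remaining splits gave at most 91. Of the 8 splits at 24 h that part every pair of a culture, too few for a share under 0.05, the highest other gave 0. The split along the sets parts no pair. With culture as a block 2632 and 1338 genes passed at 6 h and 24 h, and within sets 1978 and 1 at 6 h and 175 and 6 at 24 h.

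The responses of KO and WT cells to IFN-b differed by a direct test for 91 genes at 6 h and 57 at 24 h. The KO effect differed from the C61A effect by a direct test for 971, 65 and 247 genes at 0 h, 6 h and 24 h. The 2 effects come from different sets, so the mutation and the set are not separated in these counts. The 6 h response of WT cells differed between the sets for 63 genes. The 24 h response of BV-2 cells differed between the siRNAs for 2 genes.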

How the results depend on the processing

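The set-alone fits, the fits with culture or a crossed number as a block and those without the doubted arrays were chosen after the data were seen, the other alternatives before. Counts of genes past the threshold moved by more than 1.5 times as follows, and the cause was not tested. With set as an additive term they were 619 and 121 for the WT response at 6 h and 24 h, 446 for the KO response at 6 h and 467 for the C61A response at 24 h, 573 and 1285 for KO against WT at 0 h and 6 h, 6 and 6 for C61A against WT at 6 h and 24 h, 2 for the differing KO response at 6 h, and 471, 1638 and 578 for the KO effect against the C61A effect at 0 h, 6 h and 24 h. With no set term they were 35 and 23 (WT response), 70 and 29 (KO response), 43 (C61A response at 24 h), 245 and 1505 (KO against WT at 0 h and 24 h), 5 and 0 (C61A against WT at 6 h and 24 h), 1 and 9 (differing KO response), and 2215 and 1000 (KO against C61A effect at 6 h and 24 h), and Usp18 in untreated C61A against WT turned to 1.01. These 2 settings put WT arrays of both sets together. With the replicate number as a block they were 410 for the WT response at 24 h, 1215 and 679 (KO response), 9 and 1110 (C61A response), 1105 (KO against WT at 6 h), 2 and 29 (C61A against WT at 6 h and 24 h), 231 and 125 (differing KO response), 241 and 623 (KO against C61A effect at 6 h and 24 h), and in BV-2 119 and 107 (control siRNA response), 746 and 2051 (Usp18 siRNA response), 3 and 1456 (between siRNAs at 0 h and 24 h) and 16 (differing response at 24 h). With culture as a block, fixed, the responses at 6 h and 24 h came to 2632 and 1338 (WT), 1818 and 1413 (KO), 45 and 1842 (C61A), 132 and 135 (control siRNA) and 1061 and 2277 (Usp18 siRNA), and the differing responses to 467 and 534 (KO) and 29 (BV-2 at 24 h). As a random block they came to 2576 and 995, 1907 and 1449, 20 and 1864, 131 and 127, 1199 and 2280, 535 and 461, and 17, with 2 and 5 for C61A against WT at 6 h and 24 h and 17 for the KO against C61A effect at 6 h. Numbers pair arrays on more than a hint in WT and KO. The crossed block gave 592 (WT response at 24 h), 595 (KO response at 24 h), 16 (C61A response at 6 h), 5 and 5 (C61A against WT at 6 h and 24 h), 139 and 112 (differing KO response), 164 and 548 (KO against C61A effect at 6 h and 24 h), 78 (Usp18 siRNA response at 6 h) and 1 (differing BV-2 response at 24 h). Without the doubted arrays the counts were 1874 and 538 (WT response), 1209 and 509 (KO response), 414 (C61A response at 6 h), 998 (KO against WT at 6 h), 3, 4 and 99 (C61A against WT), 362 and 208 (differing KO response), 534, 9 and 520 (KO against C61A effect), and in BV-2 3 (Usp18 siRNA response at 6 h), 655 (between siRNAs at 24 h) and 5 (differing response at 24 h), and Usp18 in C61A against WT turned to 0.19 and 0.15 at 0 h and 6 h. On set 1 arrays only they were 40 (KO response at 24 h) and 275 and 157 (differing KO response), and on set 2 arrays only 0 and 190 (C61A response) and 0, 0 and 0 in limma (C61A against WT, with 391, 252 and 578 genes at an unadjusted p under 0.05 on all arrays). No filter gave 50 (differing KO response at 6 h), 19 (KO against C61A effect at 6 h), 78 (Usp18 siRNA response at 6 h), 161 (between siRNAs at 24 h) and 1 (differing BV-2 response at 24 h), and the stricter filter 1 (C61A against WT at 24 h), 8 (KO against C61A effect at 6 h) and 0 (differing BV-2 response at 24 h). Quantile normalization again gave 22 (15 up and 7 down, against 34 and 31) for the KO against C61A effect at 6 h and 1 for the differing BV-2 response, and median centring 1 (C61A against WT at 24 h), 39 and 37 (differing KO response) and 10 and 158 (KO against C61A effect at 6 h and 24 h). Rescaling also moved the share that rose: median centring gave 668 up and 347 down for the WT response at 6 h (604 and 622 as deposited), quantile normalization again 236 and 265 for KO against WT at 6 h (229 and 433), 86 and 29 for the Usp18 siRNA response at 6 h (73 and 68) and 513 and 442 at 24 h (474 and 662), where centring gave 71 and 26 and 494 and 430. The mean of the probe sets gave 111 for the KO against C61A effect at 6 h, and the trended prior 15 there, 1 for C61A against WT at 24 h and 0 for the differing BV-2 response at 24 h. Leaving out each array in turn, with the lone array of a group assumed to vary like the other groups, counts ran from 364 to 1703 and 54 to 427 (WT response), 12 to 1175 and 3 to 681 (KO), 0 to 26 and 63 to 887 (C61A), 175 to 1554, 22 to 1262 and 1011 to 2478 (KO against WT), 0 to 170, 0 to 6 and 0 to 21 (C61A against WT), 24 to 203 and 2 to 94 (differing KO response), 0 to 4 and 0 to 83 (differing C61A response), 256 to 1369, 0 to 611 and 42 to 414 (KO against C61A effect), 8 to 86 and 1 to 51 (control siRNA), 3 to 836 and 55 to 2176 (Usp18 siRNA), 0 to 4, 0 to 293 and 5 to 1927 (between siRNAs) and 0 to 32 and 1 to 353 (differing BV-2 response). Usp18 ran from -3.48 to 0.19 in C61A against WT untreated, from -2.17 to 0.15 at 6 h, and between the siRNAs from -0.56 to 0.52 untreated and from -0.99 to 0.40 at 6 h, turning sign without 1 array. For list shifts, camera with the preset correlation called 129 of 160 list results and an estimated correlation ended 125 of these calls, 114 of 114 of the fixed lists and 11 of 15 of the independent lists, while 31 results were called by neither, and the mean of probe sets ended 1 and added 2. An offset for linear values was not run because the values are log values.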

Other observations

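Microglia of set 2 carried transcripts of astrocytes that set 1 hardly showed. The water channel gene Aqp4 lay at 2.84 to 4.24 on the arrays of set 1 and reached 10.97 on those of set 2, and the mean of the astrocyte markers was 5.30 to 6.71 in set 1 and 6.61 to 9.92 in set 2. Within set 2 Aqp4 differed between cultures. On the arrays labelled WT replicate 1 it was 8.59 untreated, 3.08 at 6 h and 3.52 at 24 h, and on those labelled C61A replicate 2 it was 8.53 untreated, 3.24 at 6 h and 8.39 at 24 h. The 2 values out of line are those of the arrays of doubted label, whose exchange would give 3.24, 3.08 and 3.52, and 8.53, 8.59 and 8.39. At 24 h the C61A means lay above WT for 9 of 9 astrocyte markers, though Aqp4 on replicate 2 lay lower (8.39 against 9.77). The median was 0.82, and none passed in limma (578 of all genes at an unadjusted p under 0.05). Cell content was not tested.

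Cultures also differed in sex-linked transcripts. Xist, which silences 1 X chromosome in females, lay at 10.27 to 10.75 on the WT replicate 1 arrays of set 1 at all 3 times and at 5.11 to 5.43 on the replicate 2 arrays. On the KO arrays it lay at 10.33 to 10.66 (replicate 1) and 8.81 to 9.18 (replicate 2). The Y-linked gene Eif2s3y lay at 3.66 to 3.94 and 6.57 to 7.03 on the KO replicate 1 and 2 arrays and at 6.11 to 8.18 on the WT arrays of set 1, so that KO and WT cultures also differed in sex-linked transcripts. On the BV-2 array labelled Usp18 siRNA 6 h replicate 2 Eif2s3y lay at 6.64, against 2.44 to 3.22 on the other BV-2 arrays. The WT and C61A arrays of set 2 whose labels are doubted were compared by culture profile in the first part.

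The 613 genes induced by IFN-b in WT of set 1 were followed in C61A against WT of set 2. Medians were -0.63, -0.39 and 0.26 at 0 h, 6 h and 24 h. The first 2 include arrays of doubted label. The 284 genes induced in WT of both sets had medians of 0.29, 0.47 and 1.23 with the Usp18 against the control siRNA in BV-2. At 24 h camera gave p = 7.5e-49 with the preset and p = 0.0415 with an estimated correlation. Untreated BV-2 replicates with the Usp18 siRNA differed. Antiviral means were 7.20 and 8.84 (6.19 and 6.66 with the control siRNA), and Mx1 lay at 4.26 and 7.89.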
